A study of Mus musculus with 9 samples.

How the data were processed

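Total RNA of a murine MLL-AF9/NrasG12D leukaemia cell line, cultured in RPMI medium with serum and transduced with MSCV-based (LMN) vectors, was measured on 9 arrays taken at day 5. The groups were a control shRNA against Renilla luciferase, an shRNA against Eed and an shRNA against Suz12, with 3 arrays each, as the titles of the samples state. RNA was labelled with biotin by the Affymetrix whole-transcript protocol. Only the deposited processed values were used; the raw array images were not used here. The deposited values are log2 values that the authors obtained by RMA (robust multi-array average), and the version of the software and its probe annotation are not given in the sources used here. The range of the values, from 3.38 to 14.46, and array medians between 6.86 and 6.95 were checked against that unit. The labels do not say whether the 3 arrays of a group came from separate transductions or cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

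Of 34760 probe sets, 22961 were listed in the table of probe genes. Of those, 21640 carried 1 gene symbol and were used, 1321 carried several and were left out, and 11799 probe sets were unnamed here and entered only an alternative in which each probe set was tested on its own. By gene number, 21553 of the single-symbol probe sets matched a gene table of the mouse assembly GRCm38.p6, which was used only for current names and for the order of genes, and 0 symbols needed replacing. Where a gene had more than 1 probe set (954 genes), the probe set with the highest mean over all arrays stood for it, giving 19937 genes. RMA values carry no detection call, and no gene was left out for a low value.

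A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual degrees of freedom, a prior of 4.11 degrees of freedom). The contrasts were Eed shRNA against control, Suz12 shRNA against control, Suz12 shRNA against Eed shRNA, and the mean of both knockdowns against control, and a moderated F test asked which genes differed among the 3 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 across all genes of a contrast, in two-sided tests. Changes are differences of mean log2 values, folds are powers of 2 of those, and standard errors are those of the moderated fit. Genes changed by both knockdowns were those called in both comparisons with the control in the same direction. Because the comparisons share the control arrays, the overlap was set against 100 simulated data sets of unchanged groups with the observed residual spread.

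All 31 gene lists were written from general knowledge. They covered PRC2 subunits, PRC1 subunits, CDK inhibitors, p53 targets, the HoxA cluster, the HoxB, HoxC and HoxD clusters, an MLL-fusion leukaemia programme, stem and early progenitor markers, monocyte and macrophage genes, neutrophil granule and maturation genes, MHC class II genes, MHC class I presentation genes, interferon-stimulated genes, germ-layer transcription factors and signals bound by PRC2 in ES cells, imprinted genes, G1/S genes and G2/M genes. The others were cytosolic ribosomal proteins, MYC targets and nucleolar genes, NF-kB and inflammatory genes, unfolded protein and integrated stress response genes, cholesterol biosynthesis, erythroid, megakaryocyte and platelet, mast cell, basophil and eosinophil, dendritic cell, B cell, T and NK cell, and fibroblast and stromal markers, mitochondrially encoded genes and replication-dependent histone genes. Members were counted by their calls over all genes and by calls with p adjusted over the list alone. Lists with at least 5 measured members, 30 in all, were tested against the other genes with camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether the members of a list move on balance in 1 direction, were alternatives. Cdkn1a, a member of the CDK inhibitor and p53 target lists, was left out because its probe sets carry several symbols.

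The genes named in the text followed a rule. They were Eed and Suz12, the 10 genes with the largest rise and the 10 with the largest fall in each comparison with the control, the 5 largest in each direction between the knockdowns, and the 10 largest in each direction among genes called in both comparisons. For the largest changes in each comparison with the control and between the knockdowns, the arrays of the groups compared had to be fully separated. This was not required of the targets or of genes called in both comparisons. Clone names and small RNAs were counted but not named. Up to 4 members of each list with the smallest adjusted p in the mean contrast were added, with all PRC2 and CDK inhibitor genes. Other genes are said to be named after their values were seen. Groups, contrasts, lists, the naming rule and the other ways of processing and testing were fixed before the data were examined.

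Each count of genes was recomputed under alternatives, changing 1 choice at a time. These were leaving out the 40% of genes with the lowest mean, the mean of all probe sets of a gene, each probe set on its own, centring on array medians, a second quantile normalization, cyclic loess, a prior with a trend and robust estimation, array weights, a fit to only the arrays compared (for comparisons of single groups), the replicate number as a block, a fold of at least 1.5, an adjusted p under 0.01, and leaving out each array in turn. List calls were recomputed without the dim genes, after centring, after cyclic loess, with the block, without each array, with an estimated correlation and by fry. The replicate numbers did not pair the arrays: residuals of arrays with the same number correlated between -0.167 and 0.201, and those of arrays with different numbers between -0.329 and 0.271. Every count was also set against other splits of the same arrays.

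The method was tested on simulated data for each comparison with the control, with 200 changed genes among 19937 and 5 runs. For Eed shRNA against control it recovered 67.6% of genes changed 1.25-fold, 95.6% at 1.5-fold, 100% at 2-fold and 100% at 3-fold, and 5.32% of calls were unchanged genes. For Suz12 shRNA against control the shares were 66.4%, 95.6%, 99.6% and 99.6%, with 5.64% of calls unchanged genes. A shifted list was found in 5 of 5 runs of each, and 0 other lists were called by camera. Noise was drawn independently for each gene, so these runs cannot show how often camera calls lists of correlated genes wrongly. Far more genes were called in the real comparisons (4352 and 4222) than were changed here, and the adjusted threshold depends on that number. The shares recovered therefore need not hold for the real comparisons.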

Results

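Total RNA from a murine acute myeloid leukaemia cell line driven by the MLL-AF9 fusion and NrasG12D was hybridized to Affymetrix arrays on day 5 after transduction with a retroviral shRNA vector. The shRNA targeted Eed, Suz12 or, as a control, Renilla luciferase, which the cells do not carry. Each of the 3 groups held 3 arrays, 9 arrays in all. Every array gave 34760 probe set values on the log2 scale, with medians between 6.86 and 6.95 and a range from 3.38 to 14.46. After naming, 19937 genes were tested. Eed and Suz12 encode core subunits of Polycomb repressive complex 2 (PRC2), the enzyme that methylates histone H3 at lysine residues of silenced genes. Suppressing each subunit in turn asked which genes lie downstream of the complex in these leukaemia cells. The number of arrays limits the precision of every value, and the median standard error of a difference between 2 groups was 0.05 on the log2 scale.

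The spread between arrays was small beside the difference from the controls. Within groups, the standard deviation of the difference between 2 arrays across genes lay between 0.102 and 0.140, over 9 pairs. Between a knockdown array and a control array it lay between 0.230 and 0.275, over 18 pairs. An Eed shRNA array and a Suz12 shRNA array differed by 0.103 to 0.137, over 9 pairs, which was the size of the spread within groups. The first principal component carried 66.6% of the variance and placed the controls between -23.2 and -19.8 and all 6 knockdown arrays between 8.84 and 12.1.

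Each shRNA lowered its own target. Eed stood at 10.22 ± 0.07 in the controls (log2, SD, n = 3) and at 8.47 ± 0.11 under Eed shRNA, a fall of 3.36-fold (log2 change -1.75, SE 0.08, adjusted p = 3.1e-07). Under Suz12 shRNA Eed was at 10.08 ± 0.14 and was not called (-0.14, adjusted p = 0.274). Suz12 stood at 12.14 ± 0.08 in the controls and at 10.16 ± 0.11 under Suz12 shRNA, a fall of 3.94-fold (-1.98, SE 0.07, adjusted p = 5.44e-08). Under Eed shRNA Suz12 was at 11.98 ± 0.07 and was not called (-0.16, adjusted p = 0.125). The catalytic subunit gene Ezh2 changed by -0.01 in each comparison.

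**Figure D1:**
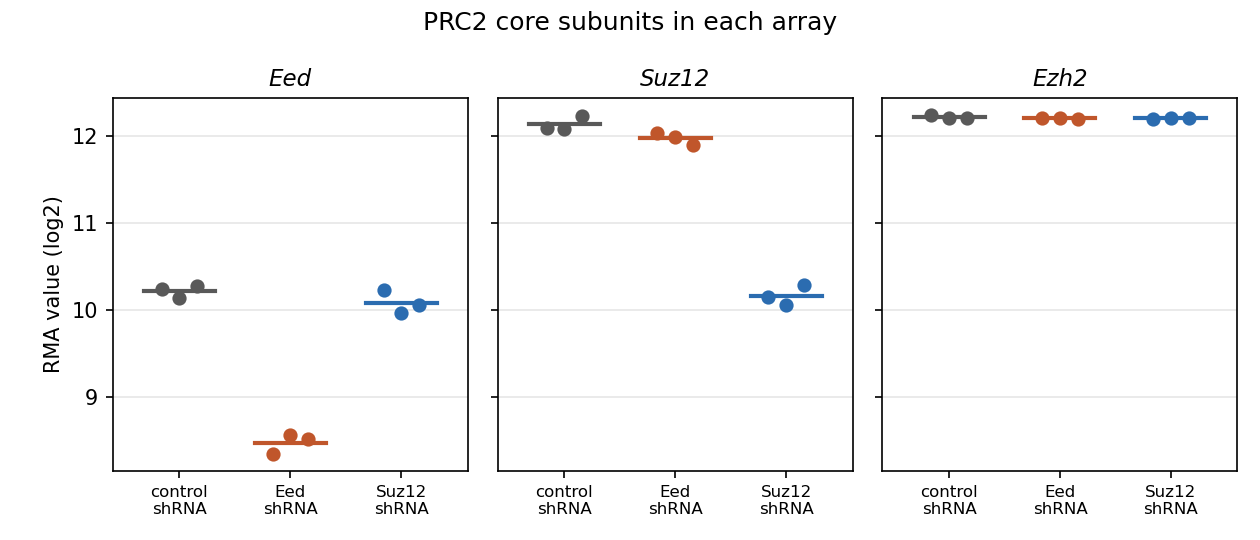
RMA values (log2) of Eed, Suz12 and Ezh2 in each of the 9 arrays, by group; points are arrays and lines are group means. The 3 Eed shRNA arrays lie below all others for Eed (mean 8.47 against 10.22 in the controls), and the 3 Suz12 shRNA arrays below all others for Suz12 (10.16 against 12.14).

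Granule and surface genes of myeloid cells were among the largest rises under Eed shRNA. The largest rise was that of Prg2, which encodes the major basic protein of eosinophil granules, at 19.9-fold (log2 change 4.31, SE 0.11, adjusted p = 2.35e-08). Mmp9, the gelatinase of neutrophil granules, rose 10.2-fold (3.34, SE 0.09, adjusted p = 2.35e-08), and the matricellular gene Thbs1 rose 9.34-fold (3.22, SE 0.14, adjusted p = 3.1e-07). The serpin gene Serpinb2 rose by 3.17 (log2) and the imprinted, retrotransposon-derived gene Peg10 rose 7.08-fold. The eosinophil peroxidase gene Epx (2.75), the macrophage surface gene Adgre4 (2.57), the activating receptor gene Cd200r3 (2.54), the neutrophil surface marker Ly6g (2.37) and Serpinb8 (2.35) completed the 10 largest rises. Apart from Eed, the largest falls were those of Bex6, at 3.06-fold (-1.61, SE 0.13, adjusted p = 1.43e-05), the purinergic channel gene P2rx3 (-1.56), Rassf4 (-1.36) and the signalling adaptor Tifa (-1.26). The receptor tyrosine kinase gene Flt3 (-1.24), the chemokine gene Cxcl10 (-1.23), the monocyte and dendritic cell transcription factor gene Irf8 (2.29-fold), Aldh1l2 (-1.18) and Tifab (-1.16) followed. A dimmer probe set of P2rx3 (mean 6.17 against 8.08) changed by only 0.004 under Eed shRNA and 0.064 under Suz12 shRNA. The fall of P2rx3 in each comparison thus rests on the probe set used.

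Over all genes, 4352 were called under Eed shRNA, 1750 higher and 2602 lower, and 6068 had an unadjusted p under 0.05. The balance of higher and lower calls depended on the scaling of the arrays. Centring on array medians gave 1379 higher and 3304 lower (29.4% higher against 40.2%), and cyclic loess gave 2141 higher and 2089 lower (50.6%). Among genes changed at least 1.5-fold, 396 were higher and 79 lower, and among those changed at least 2-fold 151 were higher and 12 lower. Under the 3 other scalings the share higher among the genes changed at least 1.5-fold stayed between 77.9% and 87.8%.

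Suz12 suppression gave much the same leading genes. Prg2 rose 25.5-fold (4.67, SE 0.11, adjusted p = 9.88e-09), Mmp9 15.1-fold (3.92, SE 0.09, adjusted p = 9.56e-09), Thbs1 7.96-fold (2.99, SE 0.14, adjusted p = 4.93e-07) and Epx 7.30-fold (2.87). The steroid dehydrogenase gene Akr1c18 rose 7.96-fold (2.99) against 4.25-fold (2.09) under Eed shRNA, a difference that was not called (0.90, adjusted p = 0.0632). Serpinb2 (2.84), Adgre4 (2.76), Ly6g (2.61), Cd200r3 (2.56) and the second major basic protein gene Prg3 (2.46) made up the rest of the 10 largest rises. After Suz12 itself, the falls were led by Bex6 (-1.45), Flt3 (-1.41), the prostaglandin dehydrogenase gene Hpgd (-1.29), Tifa (2.29-fold) and P2rx3 (-1.19), followed by the myeloid lectin gene Clec12a (-1.15), Rassf4 (-1.14), the chemokine receptor gene Ccr2 (-1.10) and Cxcl10 (-1.08).

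In this comparison 4222 genes were called, 1644 higher and 2578 lower, and 6109 had an unadjusted p under 0.05. Cyclic loess gave 2090 higher and 1892 lower (52.5% higher against 38.9%), and centring on array medians 1433 and 2980 (32.5%). Of the genes changed at least 1.5-fold, 405 were higher and 79 lower, and at least 2-fold 167 and 15. The share higher among the genes changed at least 1.5-fold stayed between 80.8% and 88.0% under the 3 other scalings.

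Both knockdowns moved largely the same genes in the same direction. Called in both comparisons were 1419 genes higher and 2113 lower, 3532 in all, which was 81.2% of the Eed shRNA calls and 83.7% of the Suz12 shRNA calls. Both thresholds and a change of at least 1.5-fold in each comparison were met by 343 higher and 57 lower genes. Prg2, Mmp9, Thbs1, Serpinb2 and Epx had the largest smaller-of-both rises, and Bex6, Flt3, Tifa, P2rx3 and Rassf4 the largest such falls. Only Leprot (-0.28 and 0.14) and Mthfd2l (-0.21 and 0.21), named after their values were seen, were called in opposite directions.

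The comparisons share their 3 control arrays, which by itself makes their changes correlate. Lists of these sizes drawn independently would share 144.3 higher genes and 336 lower genes (the product of the list sizes over the number of genes tested). In 100 simulations of unchanged groups with shared controls and noise drawn independently for each gene, the mean number of genes called in both was 0.01. With no gene changed hardly any is called, so this number cannot show how far shared controls enlarge the overlap of real calls. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.940, against a mean of 0.50 in the simulations. Their covariance was 0.0489 against 0.00192, a difference of 0.0470, and 79.5% of genes had the same sign in both comparisons against 66.7%. With 3 control arrays the controls could not be divided into separate sets of at least 2, so part of the excess may come from the shared controls.

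**Figure D2:**
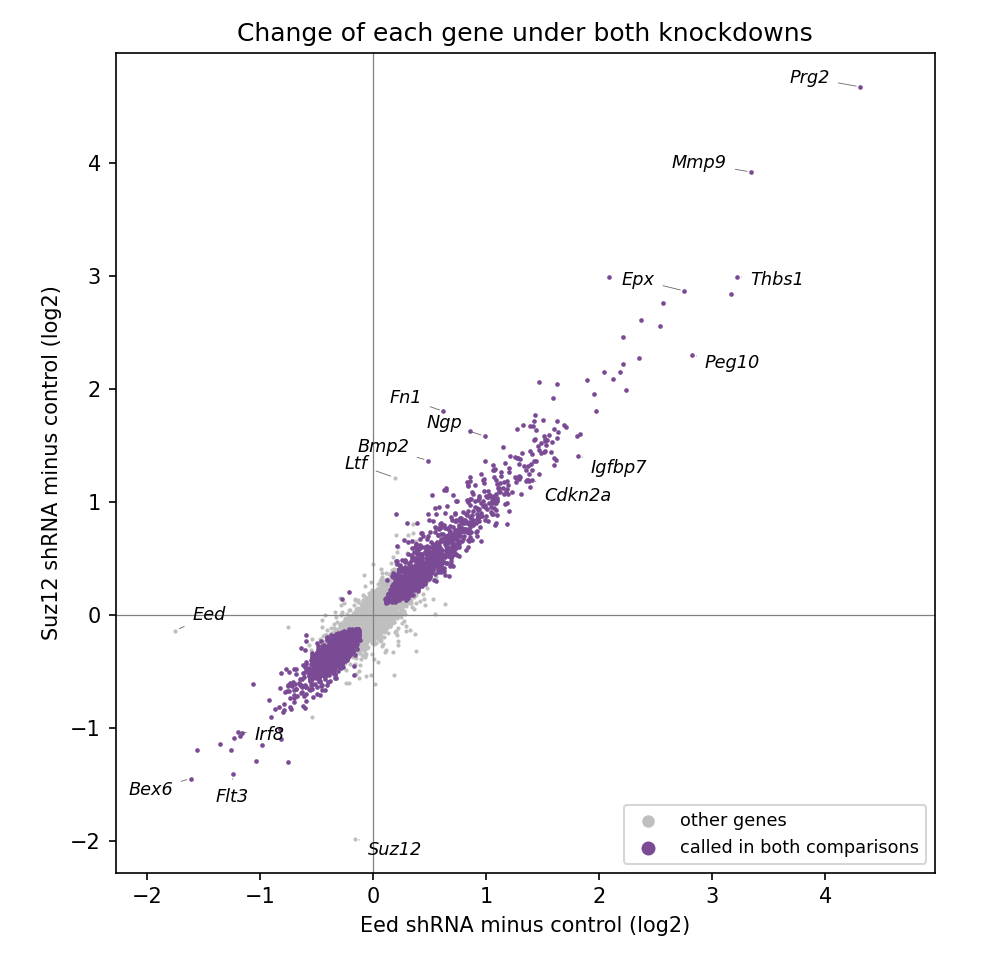
Log2 change under Suz12 shRNA against log2 change under Eed shRNA, each relative to the control group means, for 19937 genes; each point is a gene and darker points are genes called in both comparisons. Most of the largest changes lie along the diagonal, from Prg2 (4.31 and 4.67) to Bex6 (-1.61 and -1.45), while Fn1 (0.62 and 1.80) and Ltf (0.19 and 1.22) lie above it.

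The mean of both knockdowns against the controls called 5019 genes, 1939 higher and 3080 lower, of which 392 and 73 changed at least 1.5-fold, and 6597 genes had an unadjusted p under 0.05. Prg2 rose 22.5-fold in this contrast (4.49, SE 0.10, adjusted p = 3.45e-09), Mmp9 12.4-fold (3.63) and Epx 7.02-fold (2.81), and Bex6 fell by 1.53 and Flt3 by 1.33 on the log2 scale. With cyclic loess 50.6% of the calls in this contrast were higher, against 38.6%. A moderated F test found that 4202 genes differed among the 3 groups.

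Most called members of the 2 myeloid maturation lists rose, and some fell. Of 52 monocyte and macrophage genes measured, 29 were higher, 5 lower and 18 not called under Eed shRNA (30 and 5 adjusted over the list alone), and 26 were higher, 6 lower and 20 not called under Suz12 shRNA (28 and 6 adjusted over the list alone). The integrin gene Itgax rose by 1.55 and 1.60 (log2, Eed then Suz12 shRNA), the chemokine gene Ccl6 by 1.51 and 1.58, the Fc receptor gene Fcgr4 by 1.19 and 1.15, and the macrophage marker Adgre1 by 1.13 and 1.23. Irf8 and Ccr2 were among the members that fell. By camera, the list's shift was called in both comparisons, at adjusted p = 1.36e-11 for Eed shRNA (adjusted p = 0.0483 with an estimated correlation) and 2.4e-11 for Suz12 shRNA (adjusted p = 0.0618 with an estimated correlation). Of 34 neutrophil granule and maturation genes, 19 were higher, 6 lower and 9 not called under Eed shRNA (21 and 7 adjusted over the list alone), and 23 were higher, 6 lower and 5 not called under Suz12 shRNA (23 and 6 adjusted over the list alone). Mmp9, Ly6g, the cystatin gene Stfa3 (1.60 and 1.65) and the granule gene Ngp (0.99 and 1.58) were among the risen. Camera gave adjusted p = 1.95e-08 and 2.79e-13 (adjusted p = 0.0483 and adjusted p = 0.0354 with an estimated correlation). Of the 6 members that fell in each comparison, Mpo (-0.23 and -0.27), Elane (-0.30 and -0.34), Prtn3 (-0.48 and -0.43) and the transcription factor gene Cebpa (-0.73 and -0.82) were named after their values were seen.

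Among markers of eosinophils, basophils and mast cells, some granule genes rose strongly while most of the list was not called. Of 17 such markers measured, 6 were higher, 2 lower and 9 not called in each comparison (6 and 2 adjusted over the list alone in each). Prg2, Epx, Prg3 (2.22 and 2.46) and the histidine decarboxylase gene Hdc (1.33 and 1.32) had the smallest adjusted p. The list median was 0.06 and 0.03 while its mean was 0.74 and 0.75, and camera gave adjusted p = 0.000132 and 0.000258 (adjusted p = 0.0603 and adjusted p = 0.0737 with an estimated correlation). Of 12 megakaryocyte and platelet markers, 5 were higher and 7 not called in each comparison (5 adjusted over the list alone in each), with Itga2b at 1.62 and 1.38, the thrombin receptor gene F2rl2 at 1.17 and 0.98, Vwf at 0.70 and 0.62 and Itgb3 at 0.43 and 0.49. For these, camera gave adjusted p = 0.000107 and 0.000318 (adjusted p = 0.0634 and adjusted p = 0.0964 with an estimated correlation). Of 16 erythroid markers, 3 were higher under Eed shRNA (3 higher and 1 lower adjusted over the list alone) and 2 higher and 1 lower under Suz12 shRNA (2 and 1 adjusted over the list alone). Among them the transcription factor gene Gata1 rose by 0.69 and 0.68, and camera made no call (adjusted p = 0.07 and 0.14), though it called the list under Eed shRNA without control replicate 1 (adjusted p = 0.0457) or Eed shRNA replicate 2 (0.0412). After centring on array medians 1 erythroid marker was higher and 1 lower under Eed shRNA. Hbb-bh1 and Epor both lost their calls there without control replicate 3 (0.15 and 0.22) or Eed shRNA replicate 1 (0.13 and 0.23). Of 22 stem and early progenitor markers, 6 were higher and 2 lower under Eed shRNA (6 and 2 adjusted over the list alone) and 6 higher and 4 lower under Suz12 shRNA (7 and 5 adjusted over the list alone). Slamf1 rose by 0.76 and 0.63 and Gata2 by 0.74 and 0.71 while Flt3 fell, and camera gave adjusted p = 0.116 and 0.334 (0.00439 and 0.149 by fry).

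Of 4 further lists of lineage markers, camera called the fibroblast and stromal markers only, and not with an estimated correlation. Of 18 dendritic cell markers, 3 were higher and 1 lower under Eed shRNA (3 and 1 adjusted over the list alone) and 3 higher and 3 lower under Suz12 shRNA (3 and 4 adjusted over the list alone), with Itgax and Ly75 (0.56 and 0.59) risen and Flt3 fallen (camera adjusted p = 0.411 and 0.351). Of 17 B cell markers, 1 was higher under Eed shRNA (1 adjusted over the list alone) and 2 higher and 1 lower under Suz12 shRNA (2 and 1 adjusted over the list alone). The B cell scaffold gene Bank1 rose by 1.07 and 1.32 (camera adjusted p = 0.204 and 0.336). Of 19 T and NK cell markers, 2 were higher under Eed shRNA (2 adjusted over the list alone) and 1 higher and 1 lower under Suz12 shRNA (1 and 1 adjusted over the list alone). The perforin gene Prf1 rose by 0.92 and 0.74. The call of Cd28 under Eed shRNA was lost without control replicate 1 (0.25) or 3 (0.26) or Eed shRNA replicate 1 (0.25) or 2 (0.28). Camera gave adjusted p = 0.147 and 0.493 for that list (0.0171 and 0.409 by fry), whose median under Suz12 shRNA was -0.01 while its mean and camera pointed up. Of 19 fibroblast and stromal markers, 3 were higher under Eed shRNA (3 adjusted over the list alone) and 3 higher and 1 lower under Suz12 shRNA (3 and 1 adjusted over the list alone). The fibronectin gene Fn1 rose by 0.62 and 1.80 and Pdgfrb by 0.66 and 0.63, and camera gave adjusted p = 0.0161 and 0.0293 (adjusted p = 0.4 and adjusted p = 0.486 with an estimated correlation). For Suz12 shRNA that call was lost without control replicate 3 (adjusted p = 0.0993) or Suz12 shRNA replicate 2 (0.11), with cyclic loess (0.0663) and without the dim genes (0.0981). Many members of these lists lay low on the arrays. Only 5 of the 17 B cell markers and 9 of the 19 T and NK cell markers had a mean above 6.33 in at least 1 group. The same held for 11 of the 18 dendritic cell markers and 11 of the 19 fibroblast and stromal markers. This guide to background, chosen after the values were seen, is the 95th percentile of the control means of 1015 olfactory receptor genes.

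**Figure D3:**
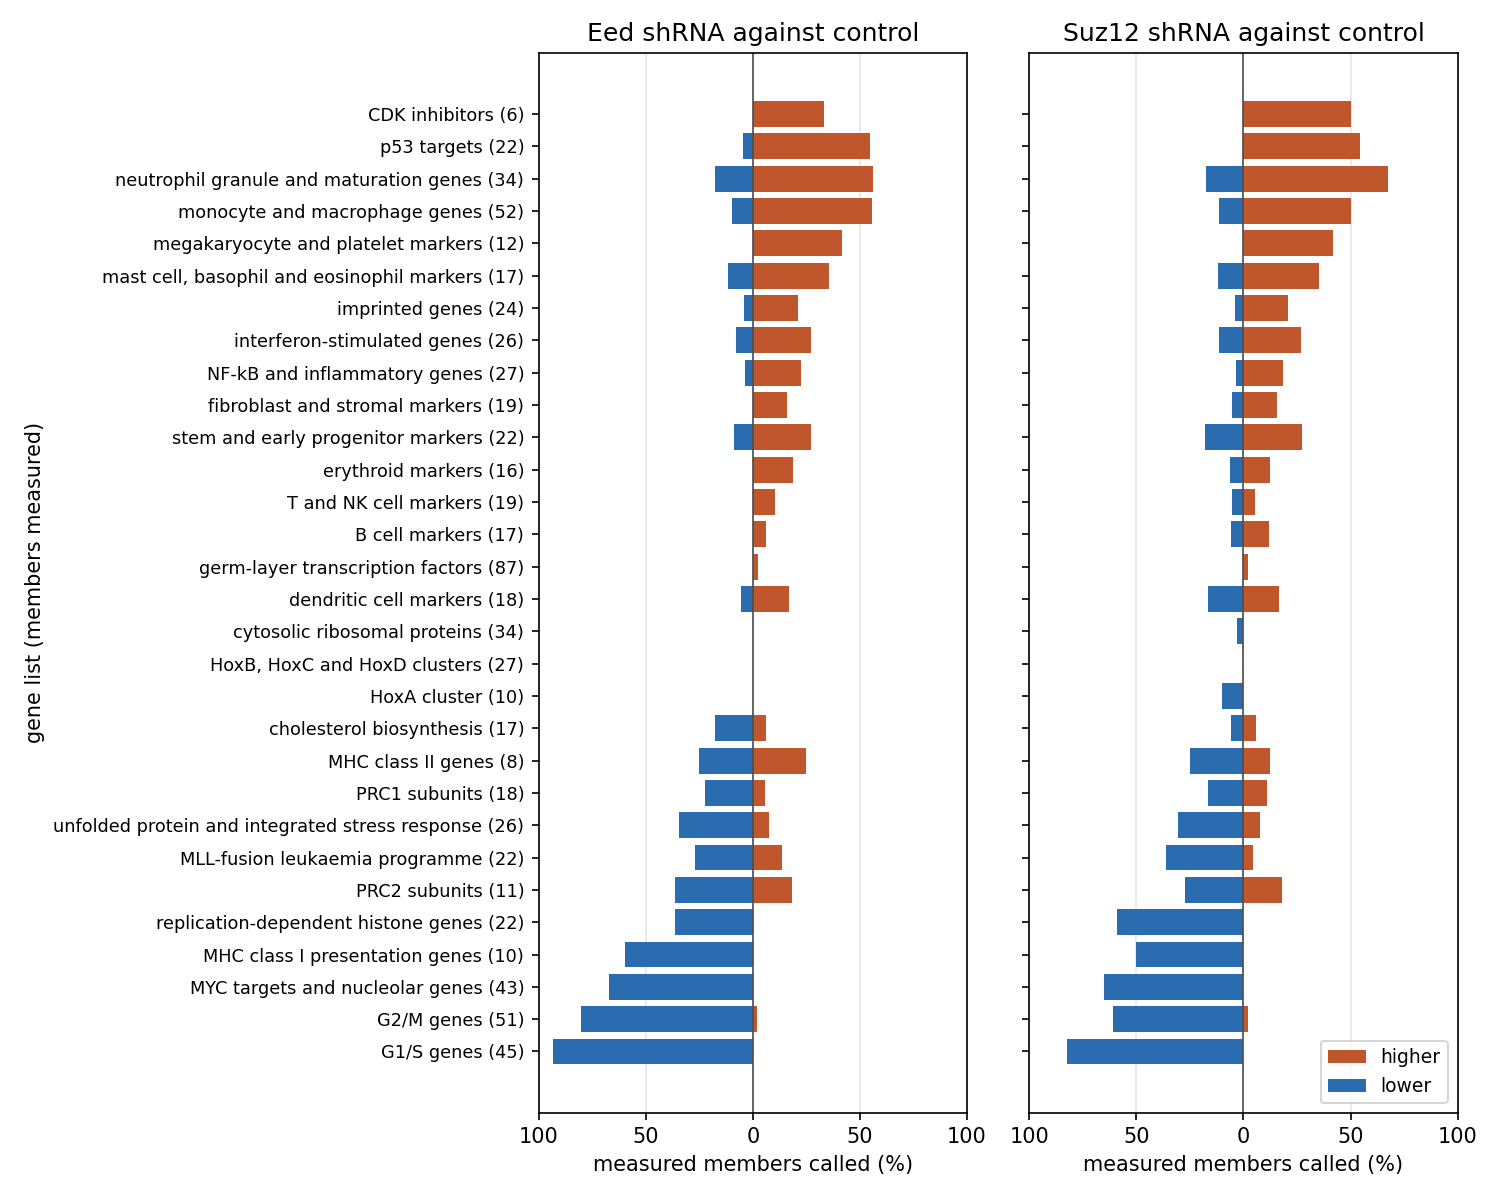
Percentage of the measured members of each gene list called higher (right) or lower (left) than the controls under Eed shRNA and under Suz12 shRNA; the number measured is in brackets. G1/S genes were lower in 42 and 37 of 45 members and monocyte and macrophage genes higher in 29 and 26 of 52, and both lists kept these directions under the 3 other scalings.

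Cell cycle inhibitor genes at the Cdkn2a and Cdkn2b locus rose. Cdkn2a, which encodes p16 and p19 proteins that act on the RB and p53 pathways and is a classic Polycomb target, rose 2.64-fold under Eed shRNA (1.40, SE 0.06, adjusted p = 1.83e-07) and 2.29-fold under Suz12 shRNA (SE of the log2 change 0.06, adjusted p = 5.32e-07). Its neighbour Cdkn2b rose 2.34-fold (1.23) and 2.12-fold (1.09). Cdkn1c changed by 0.20, which was not called, and by 0.26, a call that was lost without control replicate 2 (0.22) or 3 (0.25) or Suz12 shRNA replicate 1 (0.21) or 2 (0.24). Cdkn2d (0.12 and 0.12), Cdkn2c (0.01 and 0.10) and Cdkn1b (0.09 and -0.04) were not called. Under Eed shRNA Cdkn1c was called without control replicate 1 (0.25) or Suz12 shRNA replicate 3 (0.20), without the dim genes and with the replicate block. Cdkn2d was called in both comparisons without control replicate 3 (0.15 each), after quantile normalization (0.14 each) and after cyclic loess (0.16 and 0.17), and these scalings also called Cdkn1b under Eed shRNA (0.12 and 0.14). Of the 6 CDK inhibitor genes measured, 2 were thus higher under Eed shRNA (4 after quantile normalization or cyclic loess) and 3 under Suz12 shRNA (4 after cyclic loess), and 4 and 4 adjusted over the list alone, with camera adjusted p = 0.000347 and 0.000756 (adjusted p = 0.0483 and adjusted p = 0.0618 with an estimated correlation). Targets of the transcription factor p53 rose too. Of 22 measured, 12 were higher, 1 lower and 9 not called under Eed shRNA (16 and 2 adjusted over the list alone), and 12 were higher and 10 not called under Suz12 shRNA (14 higher and 2 lower adjusted over the list alone). Perp rose by 2.24 and 1.99, Trp53inp1 by 1.63 and 1.71, Btg2 by 0.99 and 0.96 and Zmat3 by 0.98 and 1.10. The test of the list by camera gave adjusted p = 1.95e-08 and 5.83e-11 (adjusted p = 0.0483 and adjusted p = 0.0354 with an estimated correlation).

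Proliferation lists fell by small amounts, G1/S genes nearly throughout and the other lists in part. Of 45 G1/S genes, 42 were lower and 3 not called under Eed shRNA (44 lower adjusted over the list alone), and 37 were lower and 8 not called under Suz12 shRNA (41 lower and 1 higher adjusted over the list alone). The nuclease gene Exo1 fell by 0.53 and 0.50, Tipin by 0.51 and 0.35, Dtl by 0.50 and 0.40 and Cdca7 by 0.47 and 0.50 (log2), and the list medians were -0.33 and -0.27. For G1/S genes camera gave adjusted p = 1.98e-22 and 1.89e-15 (adjusted p = 0.0603 and adjusted p = 0.111 with an estimated correlation). Of 51 G2/M genes, 41 were lower, 1 higher and 9 not called under Eed shRNA (46 and 1 adjusted over the list alone), and 31 were lower, 1 higher and 19 not called under Suz12 shRNA (42 and 1 adjusted over the list alone). The kinesin gene Kif2c fell by 0.53 and 0.40, Cdca2 by 0.44 and 0.37 and Anln by 0.41 and 0.32, and camera gave adjusted p = 6.93e-18 and 4.97e-12 (adjusted p = 0.124 and adjusted p = 0.243 with an estimated correlation). Of 43 MYC target and nucleolar genes, 29 were lower and 14 not called under Eed shRNA (33 lower adjusted over the list alone), and 28 were lower and 15 not called under Suz12 shRNA (32 lower adjusted over the list alone). Ppat fell by 0.48 and 0.50, the RNA polymerase I subunit gene Polr1b by 0.42 and 0.47, Myc itself by 0.37 and 0.42 and Gnl3 by 0.34 and 0.26. For the list, camera gave adjusted p = 2.6e-12 and 4.77e-11 (adjusted p = 0.0483 and adjusted p = 0.0618 with an estimated correlation). Of 22 replication-dependent histone genes, 8 were lower under Eed shRNA and 13 under Suz12 shRNA (11 and 16 adjusted over the list alone), among them H4c3 (-0.37 and -0.35) and H1f1 (-0.28 and -0.30), with camera adjusted p = 0.000154 and 9.67e-05 (adjusted p = 0.398 and adjusted p = 0.441 with an estimated correlation). These 4 lists kept their direction under the 3 other scalings. With cyclic loess, which gave the fewest calls, 39 and 33 G1/S genes 35 and 25 G2/M genes, 23 and 23 MYC target and nucleolar genes and 7 and 7 histone genes were lower, the last against 13 without it under Suz12 shRNA.

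Few Hox genes were called, and camera called neither the Hox lists nor the MLL-fusion programme. In the HoxA cluster, which MLL fusions activate, limma called 0 of 10 genes under Eed shRNA (0 at an unadjusted p under 0.05) and 1 under Suz12 shRNA (0 adjusted over the list alone in each). Hoxa9 changed by -0.10 and -0.07, Hoxa10 by 0.13 and 0.11, and Hoxa7 by -0.05 and -0.15, the last of which was called under Suz12 shRNA. That call was lost after quantile normalization or cyclic loess, and without control replicate 1 (-0.13) or 3 (-0.14) or Suz12 shRNA replicate 2 (-0.12) or 3 (-0.14). By camera the list had adjusted p = 0.459 and 0.702. Of 27 HoxB, HoxC and HoxD genes, limma called 0 in each comparison (0 adjusted over the list alone, 1 at an unadjusted p under 0.05 in each), and camera gave adjusted p = 0.314 and 0.336. Hoxb3 changed by 0.10 and 0.07. Hoxc4 was called higher under Eed shRNA with cyclic loess (0.17), a prior with a trend and robust estimation (0.17) or array weights (0.19). It was also called without control replicate 2 (0.21) or Eed shRNA replicate 2 (0.20). Only 10 of the 27 had a mean above the background guide in at least 1 group, so small changes of the others could have been missed. Of 22 genes of the MLL-fusion programme, 3 were higher and 6 lower under Eed shRNA (3 and 7 adjusted over the list alone) and 1 higher and 8 lower under Suz12 shRNA (2 and 8 adjusted over the list alone). Flt3, Myc and Hmgb3 (-0.43 and -0.29) fell and Cpeb2 (0.47 and 0.40) rose. Camera made no call (adjusted p = 0.355 and 0.174) while fry called the list lower (adjusted p = 0.00846 and 0.00195), and under Eed shRNA the list median was 0.01 while its mean was -0.08.

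Developmental regulators that PRC2 holds in embryonic stem cells stayed mostly where they were. Of 87 germ-layer transcription factor and signalling genes measured, 2 were higher and 85 not called in each comparison (0 and 2 higher adjusted over the list alone). Those genes were Bmp2, which rose by 0.49 and 1.37, and Tbx15, which rose by 0.30 and 0.81. Their control means (5.76 and 5.39) and Eed shRNA means (6.25 and 5.69), and that of Tbx15 under Suz12 shRNA (6.20), lay under the background guide, so the sizes of these rises are uncertain. The call of Bmp2 under Eed shRNA was lost without control replicate 2 (0.40) or Eed shRNA replicate 1 or 2 (0.43 each). Camera gave adjusted p = 0.315 and 0.299, and 54 of the 87 had a mean above the olfactory receptor guide in at least 1 group, so a small rise of the others could have been missed. Of 24 imprinted genes, 5 were higher and 1 lower in each comparison (5 and 1 adjusted over the list alone in each). The neighbours Peg10 (2.82 and 2.30) and Sgce (1.54 and 1.55) led, followed by Slc22a18 (0.41 and 0.33) and Phlda2 (0.33 and 0.27), with camera adjusted p = 0.00879 and 0.032 (adjusted p = 0.398 and adjusted p = 0.494 with an estimated correlation). For Suz12 shRNA that call was lost without control replicate 3 (adjusted p = 0.0946) or Suz12 shRNA replicate 2 (0.143), and with cyclic loess (0.131).

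Other Polycomb genes changed singly, and camera called neither the PRC2 nor the PRC1 list. Of the 11 PRC2 genes measured, 2 were higher and 4 lower under Eed shRNA (2 and 4 adjusted over the list alone) and 2 higher and 3 lower under Suz12 shRNA (2 and 4 adjusted over the list alone), the targeted gene included. The accessory subunit gene Phf19 fell by 0.43 and 0.42, Phf1 rose by 0.39 and 0.35 and Ezh1 by 0.22 and 0.24. Rbbp7 changed by -0.21 and -0.16, and its call under Suz12 shRNA was lost without control replicate 1 or 3 or any Suz12 shRNA replicate (-0.17 to -0.13). Rbbp4 (-0.14 and -0.12) was called under Eed shRNA, but not without any of those arrays or Eed shRNA replicate 1 or 2 (-0.14 to -0.11). Mtf2 (-0.08 and -0.11), Aebp2 (-0.09 and -0.07) and Jarid2 (0.03 and 0.04) were not called. Camera gave adjusted p = 0.116 and 0.218, while fry called the list, the targeted gene included, lower (adjusted p = 0.00209 and 0.0012). Of 18 genes of the sister complex PRC1, 1 was higher and 4 lower under Eed shRNA (2 and 5 adjusted over the list alone) and 2 higher and 3 lower under Suz12 shRNA (2 and 3 adjusted over the list alone). Bmi1 rose by 0.59 and 0.80 while Kdm2b (-0.33 and -0.33) and Ring1 (-0.22 and -0.21) fell. For PRC1 camera gave adjusted p = 0.411 and 0.817. Under Suz12 shRNA the PRC1 median was -0.03 and its mean 0.01, and cyclic loess gave 5 higher and 2 lower.

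Antigen presentation, interferon and inflammatory genes changed in separate directions. Of 10 MHC class I presentation genes, 6 were lower under Eed shRNA and 5 under Suz12 shRNA (6 and 6 adjusted over the list alone). The immunoproteasome genes Psmb10 (-0.59 and -0.63), Psmb9 (-0.40 and -0.52) and Psmb8 (-0.42 and -0.49) and the peptide transporter gene Tap2 (-0.35 and -0.51) fell. Camera gave adjusted p = 0.00296 and 0.00485 (adjusted p = 0.0603 and adjusted p = 0.0737 with an estimated correlation). Of 8 MHC class II genes, 2 were higher and 2 lower under Eed shRNA (2 and 2 adjusted over the list alone) and 1 higher and 2 lower under Suz12 shRNA (1 and 2 adjusted over the list alone). H2-DMa (-0.42 and -0.66) and H2-Ob (-0.56 and -0.57) fell while the invariant chain gene Cd74 (0.51 and 0.64) rose. Its call under Eed shRNA was lost without control replicate 1 (0.45) or 3 (0.43) or Eed shRNA replicate 1 (0.35). Camera made no call (adjusted p = 0.81 and 0.446) while fry called the list lower (adjusted p = 0.0286 and 0.00176), and under Eed shRNA the median was 0.01 and the mean -0.02. Of 26 interferon-stimulated genes, 7 were higher and 2 lower under Eed shRNA (8 and 3 adjusted over the list alone) and 7 higher and 3 lower under Suz12 shRNA (7 and 3 adjusted over the list alone). Ddx58 (0.76 and 0.60), Oas3 (0.82 and 0.57) and Rtp4 (0.39 and 0.57) rose and Cxcl10 fell, with camera adjusted p = 0.016 and 0.0154 (adjusted p = 0.398 and adjusted p = 0.441 with an estimated correlation). Of 27 NF-kB and inflammatory genes, 6 were higher and 1 lower under Eed shRNA (6 and 1 adjusted over the list alone) and 5 higher and 1 lower under Suz12 shRNA (5 and 1 adjusted over the list alone). The growth factor gene Csf1 (2.13-fold and 2.29-fold) and the chemokine gene Ccl4 (1.19 and 0.81) rose and Sod2 (-0.36 and -0.28) fell, with camera adjusted p = 0.0044 and 0.00492 (adjusted p = 0.56 and adjusted p = 0.568 with an estimated correlation). The list's call was lost by fry (adjusted p = 0.129 and 0.19) and, for Suz12 shRNA, without control replicate 3 (adjusted p = 0.0672) and without the dim genes (0.0576). Without the dim genes the call of interferon-stimulated genes under Suz12 shRNA was lost as well (adjusted p = 0.0576). The call of Ccl4 was lost there too without control replicate 1 (0.68) or 3 (0.59) or any Suz12 shRNA replicate (0.79 to 0.83).

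Against the controls, camera with all arrays called neither the stress response list nor the cholesterol and ribosomal protein lists. Of 26 unfolded protein and integrated stress response genes, 2 were higher and 9 lower under Eed shRNA (3 and 9 adjusted over the list alone) and 2 higher and 8 lower under Suz12 shRNA (4 and 8 adjusted over the list alone). The cystine transporter gene Slc7a11 rose by 1.63 and 1.57, while the serine and folate genes Mthfd2 (-0.37 and -0.22, the latter not called without Suz12 shRNA replicate 3 at -0.19), Phgdh (-0.34 and -0.29) and Shmt2 (-0.32 and -0.34) fell, and camera gave adjusted p = 0.19 and 0.423. Of 17 cholesterol biosynthesis genes, 1 was higher and 3 lower under Eed shRNA (1 and 3 adjusted over the list alone) and 1 higher and 1 lower under Suz12 shRNA (1 and 0 adjusted over the list alone). The number lower under Eed shRNA was 5 after centring, 1 after quantile normalization and 0 after cyclic loess. Dhcr7 and Insig1 both lost their calls there without control replicate 2 (-0.12 and -0.18) or Eed shRNA replicate 3 (-0.12 and -0.20). Under Suz12 shRNA the call of Dhcr7 was lost without control replicate 1 or 2, Eed shRNA replicate 1 or any Suz12 shRNA replicate (-0.15 to -0.12). It was also lost after quantile normalization or cyclic loess. Hsd17b7 rose by 0.32 and 0.40, and camera gave adjusted p = 0.116 and 0.336, but called the list under Eed shRNA without control replicate 1 (adjusted p = 0.0219) or Eed shRNA replicate 2 (0.0412). Of 34 cytosolic ribosomal protein genes, limma called 0 under Eed shRNA (0 at an unadjusted p under 0.05) and 1 under Suz12 shRNA, Rpl27 at -0.18 (0 adjusted over the list alone in each). That call was lost without control replicate 1 or 3 (-0.17 each) or Suz12 shRNA replicate 1 (-0.14), with cyclic loess and with the mean of its probe sets (-0.05), and camera gave adjusted p = 0.459 and 0.702. The 2 mitochondrially encoded genes measured, ND3 (0.22 and 0.15) and COX2 (0.19 and 0.14), were called higher under Eed shRNA (2 adjusted over the list alone in each comparison), though not after centring on array medians. Both calls were lost without control replicate 1 (0.21 and 0.17) or 3 (0.19 and 0.18) or Eed shRNA replicate 2 (0.15 and 0.14), and that of COX2 without Eed shRNA or Suz12 shRNA replicate 1 (0.19 each).

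The knockdowns differed from each other in few genes. Apart from Eed itself (1.61 higher under Suz12 shRNA on the log2 scale), fibronectin Fn1 was 2.26-fold higher under Suz12 shRNA than under Eed shRNA (1.18, SE 0.09, adjusted p = 0.000617), the lactoferrin gene Ltf 2.03-fold (1.02, SE 0.07, adjusted p = 0.000167), Bmp2 1.84-fold (0.88, SE 0.13, adjusted p = 0.0278) and the alternative activation gene Retnla 1.71-fold (0.77, SE 0.11, adjusted p = 0.0316). Bmp2 and Retnla had Eed shRNA means of 6.25 and 5.77, under the background guide of 6.33, so their folds rest on values near background. Apart from Suz12 itself (-1.82), the genes lower under Suz12 shRNA than under Eed shRNA were led by the anion channel gene Lrrc8a (-0.47, adjusted p = 0.00888), Igfbp7 (-0.41, adjusted p = 0.0197), Mmp19 (-0.40, adjusted p = 0.0497) and Foxred2 (-0.36, adjusted p = 0.00803). In all, 35 genes were called, 28 higher and 7 lower under Suz12 shRNA, of which 8 and 1 differed at least 1.5-fold, and 1209 genes had an unadjusted p under 0.05. The count rested on all 6 knockdown arrays, falling to 10, 8 and 11 without Eed shRNA replicate 1, 2 and 3 and to 12, 16 and 18 without Suz12 shRNA replicate 1, 2 and 3. Fn1 and Ltf kept their calls in all 9 fits without 1 array. Bmp2 (0.76 to 0.93), Retnla (0.69 to 0.78), Lrrc8a (-0.49 to -0.45), Igfbp7 (-0.43 to -0.37), Mmp19 (-0.44 to -0.34) and Foxred2 (-0.36 to -0.34) each lost theirs without any 1 of the Eed shRNA replicates, and without some of the other arrays, at the values given.

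Of the 27 genes other than Eed that were higher under Suz12 shRNA, 16 rose in both knockdowns and did so further under Suz12 shRNA. Another 3 rose under Suz12 shRNA and were not called under Eed shRNA, and 6 fell under Eed shRNA without a rise under Suz12 shRNA. Of these 27, 7 were members of the neutrophil list, against 0.0460 by chance (Fisher's exact test, one-sided, p = 1.88e-14). In fits without 1 array, made after the values were seen, the share lay between 3 of 6 (without Eed shRNA replicate 2) and 6 of 27 (without control replicate 2 or 3), with p at most 3.78e-07, and was 3 of 9 without Eed shRNA replicate 3 or Suz12 shRNA replicate 1, 4 of 8 without Eed shRNA replicate 1, and 4 of 13 and 4 of 15 without Suz12 shRNA replicates 2 and 3. Fisher's test treats genes as independent, which genes measured on the same arrays are not, so these p-values may be far too small. With an estimated correlation, camera gave adjusted p = 0.0625 for this list between the knockdowns. Of the 7, only Ltf, Camp and Ngp were called in all 9 fits. Besides Ltf, Ngp (0.59, adjusted p = 0.000617) and Mmp9 (0.57, adjusted p = 0.0352), the 7 included Camp (0.69, adjusted p = 0.000854), Lcn2 (0.40, adjusted p = 0.0138), Fcnb (0.34, adjusted p = 0.0167) and Itgb2l (0.34, adjusted p = 0.0197), the last 4 named after their values were seen. Ltf changed by 0.19 under Eed shRNA, which was not called, and by 1.22 under Suz12 shRNA. Under Eed shRNA it was called without control replicate 3 (0.25), without Eed shRNA replicate 1 (0.24), without the dim genes, with array weights (0.21) or with the replicate block. Among the genes that fell under Eed shRNA, Pip5k1a (-0.75 against -0.10), Kpna6 (-0.60 against -0.17) and Cep55 (-0.60 against -0.23) were named after their values were seen.

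**Figure D4:**
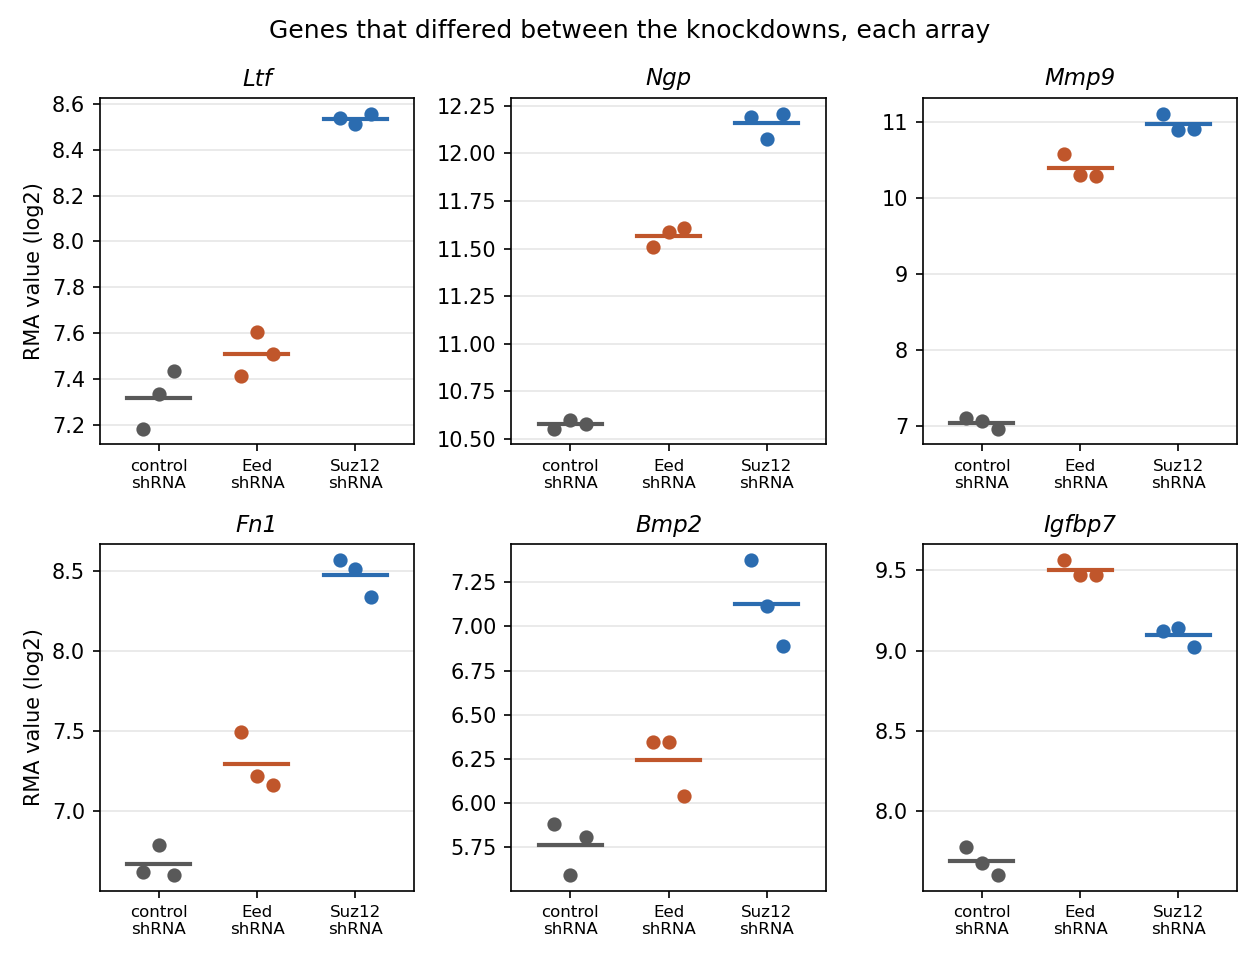
RMA values (log2) of 6 genes that differed between the knockdowns, in each of the 9 arrays; points are arrays, lines are group means, and each panel has its own vertical axis, which does not start at 0. Ltf, Ngp, Mmp9, Fn1 and Bmp2 were higher under Suz12 shRNA than under Eed shRNA, by 1.02, 0.59, 0.57, 1.18 and 0.88, and Igfbp7 differed by -0.41.

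Fewer lists were called between the knockdowns once correlation among genes was estimated. Camera called 7 of 30 lists for Suz12 shRNA against Eed shRNA, and 0 were called with an estimated correlation, against 1 by fry. The neutrophil list was higher under Suz12 shRNA at adjusted p = 1.25e-13 (adjusted p = 0.0625 with an estimated correlation), with 7 members called higher and 0 lower (11 and 0 adjusted over the list alone). G1/S genes (adjusted p = 2.98e-11) and G2/M genes (adjusted p = 2.73e-09) were shifted up, each without a member called by limma (9 and 6 higher at an unadjusted p under 0.05). Cholesterol biosynthesis genes were shifted up as well (adjusted p = 1.49e-07, 3 higher adjusted over the list alone). The PRC1 (adjusted p = 0.0366) and p53 target (adjusted p = 0.043) lists were shifted up and the stem and progenitor list down (adjusted p = 0.043), calls that were lost without Suz12 shRNA replicate 1 (adjusted p = 0.116, 0.185 and 0.0927) and without some other arrays. With an estimated correlation these gave adjusted p = 0.375 for G2/M genes and adjusted p = 0.359 for the other 5 lists. Against the controls, camera called 15 of 30 lists for each knockdown, 10 up and 5 down, and 5 for Eed shRNA and 2 for Suz12 shRNA were called with an estimated correlation, against 19 and 17 by fry.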

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

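The test of the other members of the neutrophil list was chosen after its result was seen, and the other tests of the granule genes before.

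Genes named here stood out because their response to the 2 knockdowns differed by a test of the difference itself. As the targets of the shRNAs, Eed (1.61, log2, Suz12 shRNA minus Eed shRNA) and Suz12 (-1.82) differed by construction. Fn1 (1.18), Ltf (1.02), Bmp2 (0.88), Retnla (0.77), Ngp (0.59), Mmp9 (0.57) and Tbx15 (0.51) were higher under Suz12 shRNA than under Eed shRNA, and all but Ltf were called higher than the controls under both. Igfbp7 rose less under Suz12 shRNA (-0.41), Foxred2 (-0.36) fell further under it, and Lrrc8a (-0.47) and Mmp19 (-0.40) fell under it alone. Bmp2, Retnla and Tbx15 had control means of 5.76, 4.92 and 5.39, below the olfactory receptor guide of 6.33, and rose above it under Suz12 shRNA in the case of Bmp2 (7.13) and Retnla (6.55). Under Eed shRNA Bmp2 (6.25) and Retnla (5.77) were still below it, as was Tbx15 in every group, so their differences rest on values near background. The calls of Bmp2 (0.76 to 0.93), Retnla (0.69 to 0.78), Lrrc8a (-0.49 to -0.45), Igfbp7 (-0.43 to -0.37), Mmp19 (-0.44 to -0.34) and Foxred2 (-0.36 to -0.34) were lost without Eed shRNA replicate 1, 2 or 3, and each also without at least 1 Suz12 shRNA array. These ranges cover only the fits without 1 array in which the call was lost. Mmp9 kept its call without Eed shRNA replicate 1 and lost it in every other fit without 1 array. Tbx15 was not followed in these fits.

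The late granule genes Ltf, Camp and Ngp were picked from the neutrophil list after their values were seen. A uniformly larger response to Suz12 shRNA would raise all changes alike, but over the 400 genes changed at least 1.5-fold in both comparisons the median ratio of the Suz12 to the Eed change was 0.996 (bootstrap 95% interval 0.981 to 1.01, 2000 draws), against 6.33 for Ltf, 4.44 for Camp and 1.60 for Ngp. Ltf and Camp are not among the 400, and their ratios are imprecise because their Eed changes were small (0.19, not called, and 0.20). For these 3 genes a difference confined to 1 array is excluded. The lowest of the 3 differences over the 9 fits without 1 array was 0.56, with a limma adjusted p of at most 0.0101. Of the 7 neutrophil genes called between the knockdowns, only these 3 were called in all 9 fits. The exclusion therefore does not extend to the others. The other 31 members of the neutrophil list had a median difference of 0.0492 (0.0263 to 0.0807). Of these 31, 23 were higher and 4 were called higher. The permutation p, one-sided, was 1e-04, the smallest that 10000 random lists can give. The other members were thus slightly higher as a set too. A smaller median among them follows from setting aside 3 genes picked by their values. It therefore cannot decide whether a shift of the whole list was the cause. An effect of 1 hairpin on other transcripts, the depth of each knockdown and a role of Suz12 apart from Eed remain open and were not tested, since the labels name 1 shRNA group per gene.

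Other splits of the same arrays show which counts could arise without the groups. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In fits to the 6 arrays compared, the real split called 3857 genes for Eed shRNA, 3664 for Suz12 shRNA and 29 for Suz12 against Eed shRNA, and the highest other split called 0 in each; 1 of 10 splits gave as many in each. For lists the real split called 15, 15 and 8 and the highest other split 11, 13 and 9, and 1, 1 and 3 of 10 splits gave as many. The median over the other splits was 7, 7 and 4 lists. For the mean of both knockdowns, fits with 2 groups were made (knockdown and control, where the fit with 3 groups called 5019). As many as the real 5026 genes were called in 1 of 84 splits of the 9 arrays, and the highest other split called 6. This excludes chance only as far as the arrays are separate samples. If the 3 arrays of a group came from 1 culture, which the labels leave open, a difference between cultures is not excluded. For lists, 4 of 84 splits gave as many as the real 15, and the other splits gave a median of 6 and at most 19. The share lies narrowly under 0.05, the limit set for these tests. With 3 other splits at or above the real count, it does not firmly exclude chance.

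For the test among 3 groups, 1 of 100 splits drawn gave as many as the real 4202 genes. Chance is excluded only for the difference between controls and knockdowns. The highest other split gave 4178, and it was 1 of 4 that kept the control arrays together, so it still set knockdowns against controls, while splits that mixed the controls gave at most 3. For genes changed by both knockdowns, 1 of 100 splits drawn gave as many as the real 3532, and chance is excluded for that same difference only. The highest other, 3458, was the 1 drawn split that kept the controls together, and every split that mixed them gave 0 (limma calls in both comparisons). The large values come from the structure of the samples, in which controls and knockdowns stand apart and the knockdowns nearly coincide. These splits therefore cannot show how far the knockdowns share changes beyond their shared controls. As above, they do not exclude a difference between cultures.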

How the results depend on the processing

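No alternative here was chosen after the data were seen. Against the controls, counts of called genes stayed within 1.5 times their value under every other filter, probe set rule, scaling, prior and weighting tried, and most changes came from stricter thresholds, which by construction call fewer genes. Requiring a fold of at least 1.5 left 475 genes for Eed shRNA, 484 for Suz12 shRNA, 9 between the knockdowns, 465 for the mean of both, 400 for both knockdowns and 557 among the 3 groups. An adjusted p under 0.01 left 2856, 2626 and 14 genes, 2244 for both knockdowns and 2749 among the 3 groups.

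The 35 genes called between the knockdowns were the most dependent on the processing. Testing each probe set on its own left 9 and array weights gave 54; the cause was not tested. Leaving out 1 array gave between 8 (without Eed shRNA replicate 2) and 37 (without control replicate 3). Without 1 array the counts for Eed shRNA lay between 3428 and 4238, for Suz12 shRNA between 3375 and 4100, for the mean of both between 4087 and 4837, for both knockdowns between 2857 and 3369, and among the 3 groups between 3246 and 3898.

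With the replicate block the counts were 4242 for Eed shRNA, 4049 for Suz12 shRNA, 25 between the knockdowns, 4888 for the mean of both, 3417 for both knockdowns and 4010 among the 3 groups. Among the named genes, the block ended the calls of Retnla and Mmp19 between the knockdowns. It also ended those of Rbbp4 and COX2 under Eed shRNA and of Rbbp7, Dhcr7 and H2bc8 under Suz12 shRNA. Under Eed shRNA it gave calls to Cdkn1c, Ltf and Rhd.

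List calls depended on the correlation assumed among genes. Without the dim genes 12 of the 15 lists called for Suz12 shRNA remained, the interferon, NF-kB and fibroblast lists being lost. With an estimated correlation 5 lists were called for Eed shRNA, 2 for Suz12 shRNA, 0 between the knockdowns (7 by camera at its preset correlation, 1 by fry) and 5 for the mean of both. Between the knockdowns, leaving out the dim genes gave 4 lists and fry 1, and fits without 1 array gave 5 to 9; the cause was not tested. Without 1 array, 15 to 17 lists were called for Eed shRNA, 12 to 15 for Suz12 shRNA and 14 to 16 for the mean of both.

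Of 310 values of named genes, 245 were called, of which 216 kept their call and sign under every alternative tried for them and 29 lost it in at least 1. Another 18 values gained a call, and 0 reversed. RMA values carry no detection call, so genes near the olfactory receptor guide of 6.33 (95th percentile) can hide changes in the background. Above that guide lay the means of 13513 genes in at least 1 group.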

Other observations

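The tests of the eosinophil genes, the gene-order tests without possible relatives, the name-stem test, the count of receptor families and the olfactory receptor guide were chosen after the values were seen; the other tests of gene order were written before.

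Among receptor genes of myeloid cells, those with names in Cd200r and Cd300 were chosen after their rises were seen and were counted without a test of either family. All 4 measured genes whose names start with Cd200r were called higher in both knockdowns: Cd200r3 (log2 2.54 under Eed shRNA, 2.56 under Suz12 shRNA), Cd200r1 (1.69, 1.68), Cd200r4 (1.38, 1.24) and Cd200r2 (1.36, 1.28). Of 8 measured genes whose names start with Cd300, 7 were called higher in both and 0 lower, led by Cd300lf (1.47, 1.25), Cd300e (1.04, 0.96) and Cd300ld (0.99, 0.97), while Cd300lg (0.18, 0.06) was not called. These counts were the same under the 3 other scalings. A search of 875 name stems with at least 4 members called 1, the stem Cd (16 of 94 genes risen at least 1.5-fold, Fisher's exact test, one-sided, adjusted p = 9.57e-08), which joins unrelated surface molecules by name alone.

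Single genes of lipid mediators and lipid handling changed too, named after their values were seen and not tested as a group. The lipoxygenase gene Alox15 rose by 1.43 and 1.77, the acyltransferase gene Mogat2 by 2.13 and 2.09, the lipase gene Lpl by 0.86 and 0.97 and the prostaglandin D synthase gene Hpgds by 0.93 and 0.93 (log2, Eed then Suz12 shRNA), while Hpgd, which degrades prostaglandins, fell by 1.04 and 1.29. Tbxas1, the thromboxane synthase gene, rose by 0.63 and 0.39.

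The eosinophil granule genes Prg2, Prg3 and Epx rose together, and 1 technical and 1 cellular reading were tested. Signal shared with the abundant paralogue Mpo at Epx is excluded as the cause, because Mpo itself changed by -0.25 over both knockdowns. Eosinophils as a separate fraction of the knockdown cultures cannot be told apart from a rise within the leukaemia cells. Of the eosinophil surface markers, Il5ra rose by 0.87 over both knockdowns (limma adjusted p = 4.29e-05). It stood at 5.37 in the controls, 6.11 under Eed shRNA and 6.37 under Suz12 shRNA. Siglecf (-0.11) and Ccr3 (0.01) were not called, and the median of the 3 changes was 0.00573. Ccr3 lay below the olfactory receptor guide of 6.33 in every group, and Il5ra in all but the Suz12 shRNA group. Siglecf stood at 8.80 in the controls already, so a small share of eosinophils could be hidden. The rise of Prg2, Prg3 and Epx may be a derepression of granule genes in the leukaemia cells, which the design does not separate from a fraction of eosinophils.

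Genes that rose at least 1.5-fold over both knockdowns lay next to one another more often than the order of expressed genes gives. Among 18562 genes placed in order, 388 rose and formed 42 neighbouring pairs, against a mean of 9.26 and a highest of 23 in 10000 permutations within classes of level (permutation p = 1e-04, one-sided, the smallest they can give). Signal shared between paralogues that lie side by side does not account for it all, since 22 pairs had unlike names, against a mean of 8.69 (permutation p = 4e-04), and 18 remained without 4 pairs of possible relatives (permutation p = 0.0039) and 16 without 6 such pairs, of which Slamf1 and Cd84 of the SLAM family were 1 (permutation p = 0.0153). Pairs of unlike names included Sgce and Peg10, Cd9 and Vwf, Bmp2 and Hao1, and Lpl and Slc18a1, and pairs of like names included Prg2 and Prg3 and Cdkn2a and Cdkn2b. The 70 genes that fell formed 1 pair, against a mean of 0.30 (permutation p = 0.259), too few to compare with the risen genes, and no biological explanation of the neighbours was tested.

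Small nucleolar RNAs varied between arrays in a way the groups do not fully explain. Over 51 such genes the median deviation from the gene means was -0.37 in Suz12 shRNA replicate 2 and 0.31 in control replicate 2. Under Suz12 shRNA 10 were called lower and under Eed shRNA 5 lower and 1 higher, and between the knockdowns limma called 0.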
